A study of Mus musculus and blank sample with 768 samples.

How the data were processed

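Single cells from mouse tumours, lymph nodes and blood were sorted by FACS into 96-well plates and amplified with a modified SMART-seq2 protocol, which makes full-length cDNA and adds no molecular identifiers. The cDNA went through 20 amplification cycles, and libraries were made with Nextera XT. The deposited tables hold raw read counts per gene, made by the authors from reads aligned to the mouse genome build mm10. The submitters' processing notes name FastQC 0.11.4, STAR 2.4.1b and Subread 1.4.6-p2, without stating which setting was used for which step. Every value was checked to be a whole number of 0 or more, so the tables were treated as counts that had not been normalised. A count of PCR reads is not a count of molecules, so every interval and floor given here covers counting error only.

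Each of the 768 wells was matched to its label by the plate, well and index in its name, and 0 columns were left without a sample. The gate and tissue in the labels set the groups. No label names an animal, so the cells of a group were treated as 1 sample and not as replicates. No test between groups was run for that reason, and no p-value is given. Levels are CPM, the reads of a gene scaled to 1000000 reads, of the summed counts of a group with exact Poisson 95% intervals, and shares of cells carry exact Clopper-Pearson 95% intervals. For a share of 0, the limit given in place of an interval is 3 cells over the number of cells. Ratios are log2 of CPM plus a pseudocount of 1 CPM. A fold against a group with 0 reads was computed against a floor of 3 reads over the group and is given as a lower bound.

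Both tables list the same 51826 rows, and 92 rows that shared a symbol with another were summed into it, which left 51734 symbols. A cell was kept with at least 50000 reads in genes, at least 1000 genes with a read and at most 25% mitochondrial reads. No doublet caller was run, because cells were sorted singly into wells and such callers model droplets. A gene counted as measured in a comparison with at least 1 CPM and reads in at least 5% of cells in one of the groups. Gene positions are from GENCODE vM21 on GRCm38, the assembly that mm10 also denotes. The counts are per gene, so values refer to whole genes and not to single exons.

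The gene lists, the comparisons, the rule for naming genes and the alternative settings for list medians and shares were fixed before the data were examined. Those for the numbers of genes, cells of named clusters alone and pool C left out, were chosen afterwards. The rule took the 10 genes with the highest and the 10 with the lowest ratio in each comparison. They had to have at least 20 CPM and reads in at least 25% of cells in the higher group. They also had to be at least 2-fold apart both by summed reads and by the mean of per-cell CPM, in the same direction on every plate or pool pair with at least 5 cells of each group. Genes with predicted names, ribosomal and mitochondrial genes were not named. Ptprc, Pecam1, Csf1r and Prox1 were always named, and up to 4 examples per list were taken by the size of their ratio. Results for some single genes are not reported here.

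The 34 lists hold 259 genes. They cover endothelial cells in general and blood, lymphatic, arterial, venous, capillary, high endothelial venule, angiogenic tip and lymphatic valve endothelium. Lists for the sinus floor, sinus ceiling and medullary lymphatic endothelium of lymph nodes were added to these. Other cell types were covered by lists for macrophages, inflammatory and alternative macrophage activation, haematopoietic cells, T, B, plasma, NK and dendritic cells, neutrophils, platelets, erythroid cells, fibroblasts or pericytes, epithelium and melanocytes. State lists covered endothelial-to-mesenchymal transition, proliferation, MHC class II, interferon response, hypoxia, dissociation stress and lymphangiogenic signalling. A list is described by how many measured members were at least 2-fold apart, by its median ratio and by the percentile of that median among 10000 random lists matched on expression. The genes of a random list were drawn independently of each other. Where list members vary together between cells, an extreme percentile can therefore overstate how unusual a median is. The interval of a list median comes from the order of its members and is given from 6 members up. Where members had 0 reads in one group, the median with those genes at their bound is given where it differs by more than rounding.

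Cells were clustered separately in the tumour table and in the lymph node and blood table, without the genes of the lists. The steps were 2000 variable genes, 20 principal components, 15 neighbours and Leiden clustering at a resolution of 1. The rule that names a cluster was set after the data had been seen. It asks that at least 3 markers of a class be found in at least 30% of the cluster's cells and leaves a cluster unnamed when 3 or more of its 10 leading genes are predicted, ribosomal or mitochondrial. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for scaling factors only.

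The steps were tested on simulated data with the sizes of the tumour CLEC and EC groups, with 200 of 4093 genes changed. Of 50 genes changed 2-fold, 50.0% met the rule, and of 50 genes changed 4-fold, 100.0% did, with a median log2 ratio of 2.12. A blood endothelial list moved 4-fold gave a median of 2.03, and a list left unmoved gave 0.03. Of 25 simulated lymphatic cells among 253, 25 were placed in a lymphatic-like cluster, and 0 of the other cells were. These 25 were drawn around the mean of lymph node GFP+ cells with Prox1 reads and the others around the tumour mean. They thus also differed by tissue and plate, so this cannot show whether lymphatic cells of a tumour would be set apart. In 5 simulated runs with no gene changed, 201 to 236 genes still met the rule, below but near the 242 that met it between the real tumour gates. The simulated spread between cells was altered once after a first version gave higher numbers. Because of this, the gates of the real cells were also shuffled within each comparison 100 times, a step added after the simulation had been seen. Shuffled tumour cells gave 40 to 87 genes, fewer than the simulation. The cause of this was not tested. The shuffles measure what sampling of cells gives and do not test between animals.

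The alternatives were TMM and median-of-ratios scaling, equal weight for cells, no cell filter and a stricter one (250000 reads and 2000 genes), and a pseudocount of 5 CPM. Further ones were no filter and a higher filter on low genes (10 CPM and 10% of cells), thinning of each cell to 100000 reads, other clustering settings, cells of named clusters alone, and leaving out each plate or pool. The CPM scaling placed the median of all measured genes at -0.12 for tumour CLEC over tumour EC, where TMM placed it at 0.01, and at -1.40 for blood over lymph node GFP+ cells, where TMM placed it at -1.63. For lymph node GFPlow over GFP+ cells TMM moved it to -0.11 from 0.00. No direction is given for a list whose median lies within this shift of 0.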

Results

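The data were read counts per gene for 768 wells of mouse cells from tumours, lymph nodes and blood, 2 of which were left empty. Cells were gated on CD45, a leukocyte surface protein encoded by Ptprc, on CD31, an endothelial adhesion protein encoded by Pecam1, and on GFP. GFP+ endothelial cells (CD45-, CD31+) are named in the labels as cells of the Csf1r lineage and are called CLEC here. Csf1r encodes the receptor for the macrophage growth factor CSF1. Tumour CLEC filled plates KM3 and KM4 (96 wells each). GFP- tumour endothelial cells, called tumour EC, filled plate KM2 (96 wells), and tumour macrophages (CD45+, CD31-, GFP-) filled plate KM1 (96 wells). Lymph node (LN) endothelial cells came in pools. Pools A, B and C held 48, 36 and 32 GFP+ wells and as many GFP- wells, pools B, C and D held 19, 32 and 72 GFPlow wells, and 27 wells held GFP+ cells from blood.

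Wells with a cell held 3 to 3123112 reads in genes, and 592 of 766 cells passed the filter. These were 84 and 85 tumour CLEC on plates KM3 and KM4 with a median of 805864 reads, 84 tumour EC with 827490, 81 macrophages with 867486, 98 LN GFP+ cells with 941920.5, 74 LN GFP- cells with 609243.5 and 79 LN GFPlow cells with 1238819. Of the 27 blood wells 7 passed, with a median of 816359 reads, and 20 fell under the gene minimum. No group has a replicate, because no label says which animal a cell came from. A group is therefore 1 sample, and no difference below was tested against a spread between animals.

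**Figure D1:**
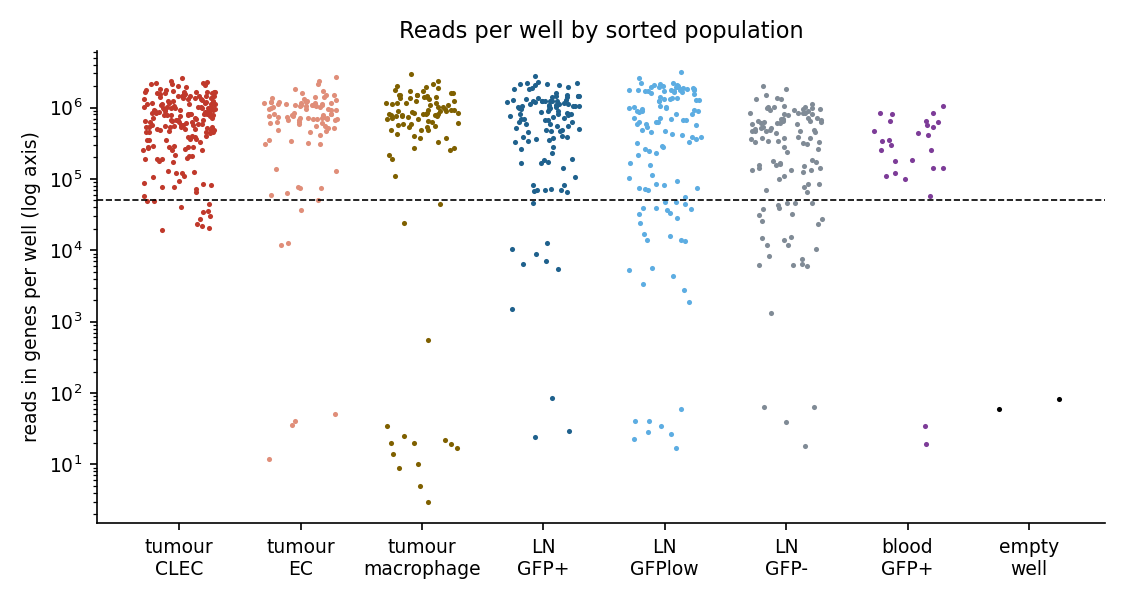
Reads in genes per well (log axis) for each sorted population, 1 point per well, with the minimum of 50000 reads as a dashed line. Wells with a cell span 3 to 3123112 reads, and the 2 empty wells hold 59 and 82.

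In the tumour the gate genes followed the sort. Pecam1 (chromosome 11, 106654217 to 106750628, minus strand) had reads in 97.04% of tumour CLEC, 97.62% of tumour EC and 13.58% of macrophages. Ptprc (chromosome 1, 138062861 to 138175708, minus strand) had reads in 91.4% of macrophages and in 0 tumour CLEC and 0 tumour EC, which allows shares of up to 1.78% and 3.57%. Csf1r (chromosome 18, 61100598 to 61132149, plus strand) was at 1384 CPM in macrophages (1376 to 1393) and at 1.44 CPM in tumour CLEC (1.26 to 1.65), with reads in 3.55% of those cells. These genes serve as checks on the sort and not as findings.

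**Figure D2:**
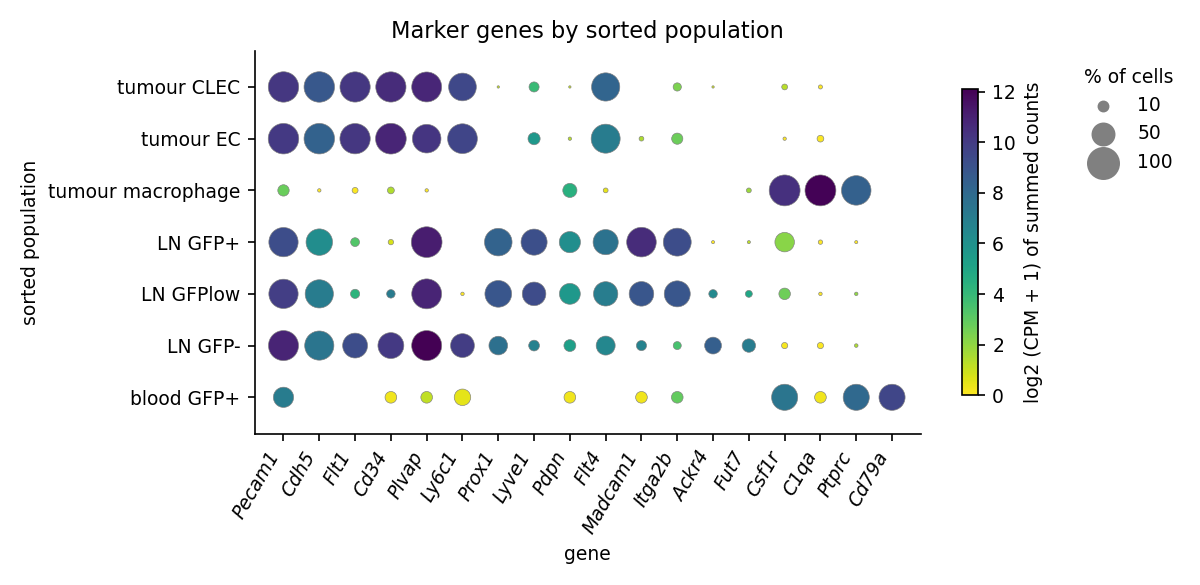
Level (colour, log2 of CPM plus 1 of summed counts) and share of cells with a read (dot area) of 18 marker genes in 7 sorted populations. Prox1 has reads in 79.6% of LN GFP+ cells and in 0.59% of tumour CLEC, and Flt1 in 8.16% and 95.9%.

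Tumour CLEC were compared with tumour EC to ask how endothelial cells of the Csf1r lineage differ from their neighbours in the same tissue. Blood endothelial genes were at like levels in both populations. Of the 13 members of that list 11 were within 2-fold, with a median log2 ratio of 0.01 (-0.20 to 0.33). Flt1, a VEGF receptor, was at 1180.3 CPM in CLEC and 1171 in EC, and Cd34, a sialomucin of vascular endothelium, at 1582 and 1824. All 12 pan-endothelial genes, all 7 venous genes, 10 of 12 angiogenic tip genes and 9 of 12 proliferation genes were also within 2-fold, with medians of -0.06, -0.11, -0.04 and -0.07.

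Of 13 lymphatic endothelial genes only 6 were measured in these tumour cells. Their median was -0.50 (-4.20 to 3.75), with 2 members at least 2-fold higher in CLEC and 3 lower. Flt4, the VEGFR-3 gene, was at 292.5 CPM in CLEC (289.8 to 295.2) and 133.2 in EC (130.7 to 135.8), with reads in 83.4% and 88.1% of cells, or 80.2% and 82.9% with cells thinned to 100000 reads. Maf, a transcription factor gene, was at 13.02 CPM in CLEC (12.5 to 13.6) and 0.04 in EC (0.01 to 0.11). Ccl21a, which encodes a chemokine that guides dendritic and T cells, was at 15.2 CPM in CLEC and 296.9 in EC, a log2 ratio of -4.20 that rests on reads in 2.37% and 9.52% of cells. Lyve1, a hyaluronan receptor gene, was at 14.04 and 49.96 CPM, a ratio of -1.76.

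Of 10971 measured genes, 0.94% were higher in tumour CLEC by the naming rule and 1.27% lower. Fabp4 (chromosome 3, 10204088 to 10208576, minus strand), which encodes a fatty acid binding protein, had the highest ratio. It was at 128.1 CPM in CLEC (126.3 to 129.9) and 3.76 in EC (3.34 to 4.22), a log2 ratio of 4.76. Reads of it were in 34.3% and 5.95% of cells, or 32.9% and 4.88% when thinned, and in 0 macrophages. Aqp1 (chromosome 6, 55336432 to 55348555, plus strand), a water channel gene, was at 105.3 and 11.2 CPM, a ratio of 3.13. Kcnj8 (chromosome 6, 142564837 to 142571614, minus strand), a subunit of an ATP-sensitive potassium channel, was at 195.3 and 26.3 CPM, a ratio of 2.85. Sipa1l2, Dhx9, Slc6a6, Kctd12, Brd1, Maml1 and Sympk followed, with ratios of 2.34 down to 1.92. Among the lower genes, Tbx1 (chromosome 16, 18580979 to 18590671, minus strand), a T-box transcription factor gene on the lymphatic list, was at 7.72 CPM in CLEC (7.28 to 8.17) and 58.7 in EC (57.01 to 60.43), a ratio of -2.78. Tmem87a, Wfdc1, Ifi204, Chka, Itm2a, Tmem214, Scgb3a1, Lpcat4 and Lhfp followed, with ratios of -2.44 to -1.94. Itm2a and Scgb3a1 also lead a blood-like cluster that held 21.3% of CLEC and 40.5% of EC. Whether their ratios follow this mix of cells was not tested.

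Of 4 measured MHC class II genes 3 were at least 2-fold higher in CLEC, with a median of 1.32 at percentile 100 of the random lists. H2-Ab1 was at 109.7 CPM in CLEC and 50.7 in EC, with reads in 27.2% and 35.7% of cells, so the shares do not follow the levels. Of 10 interferon response genes 2 were at least 2-fold lower in CLEC and 8 within 2-fold, with a median of -0.78 (-1.13 to -0.20) at percentile 0.09. Ifit1 was at 3.89 and 21.3 CPM. The 7 measured lymphangiogenic signalling genes had a median of 0.33 (0.07 to 1.51) at percentile 99.4, with 2 at least 2-fold higher. These were Flt4 and Vegfc, which encodes a ligand of VEGFR-3 and was at 59.3 and 20.2 CPM. The capillary list had 1 of 3 measured genes higher, Gpihbp1, at 697 and 299.1 CPM. The lymphatic valve list had 1 higher (Itga9, a ratio of 1.34) and 2 lower (Gata2, -1.28, and Gja4, -1.25). Arterial genes had 2 higher and 2 lower of 9, hypoxia genes 2 lower of 9, dissociation stress genes 1 lower of 10, and genes of endothelial-to-mesenchymal transition 1 higher of 6.

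Markers of B, NK and dendritic cells, neutrophils, erythroid cells, epithelium, melanocytes and alternative macrophage activation had no measured member in the tumour endothelial cells, and those of NK cells and melanocytes had none in any comparison. With gates shuffled over the cells, 40 to 87 genes met the rule, or 0.36% to 0.79% of the measured number, against 2.21% with the real gates, and Fabp4 and Tbx1 alone lay beyond the highest and lowest shuffled ratios (4.53 and -2.68). No plate held both gates, so a difference between the plates and a difference between the gates cannot be told apart here. The median of the lymphatic list ranged from -1.73 with the stricter cell filter to 0.76 with the higher filter on low genes.

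**Figure D3:**
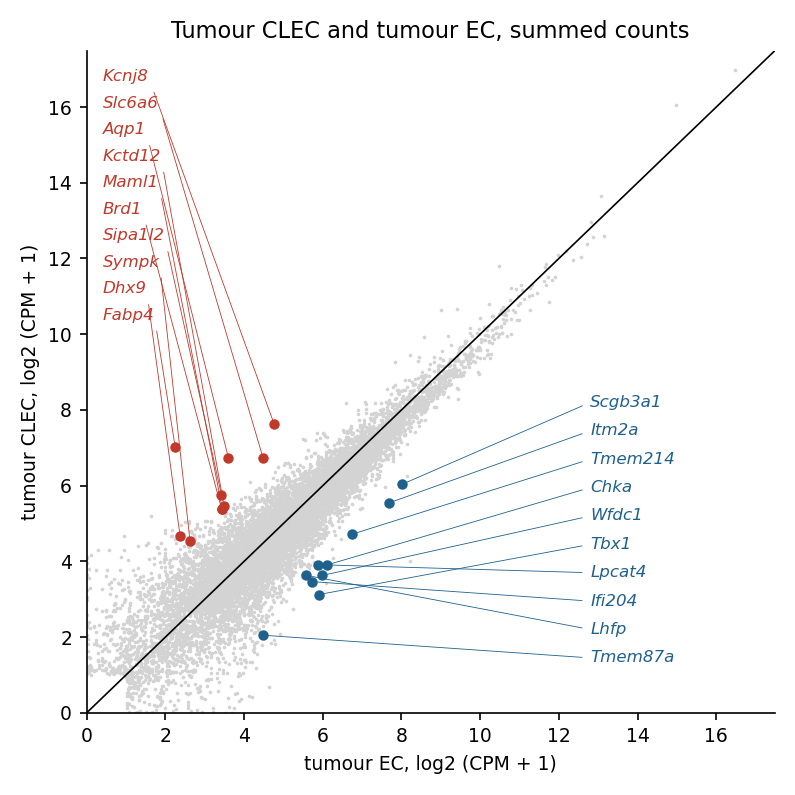
Level of each of 10971 measured genes in tumour EC (horizontal axis) and tumour CLEC (vertical axis), both as log2 of CPM plus 1, with the line of equal levels. Genes named by the rule are in red where higher in CLEC (Fabp4 at 128.1 against 3.76 CPM) and in blue where lower (Tbx1 at 7.72 against 58.7).

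Tumour CLEC were compared with tumour macrophages, because the lineage that labels the CLEC is named for a macrophage gene. All 16 macrophage genes were lower in CLEC, with a median log2 ratio of -9.23 (-12.52 to -8.47), or -12.63 with genes at 0 reads at their bound. Lyz2, the lysozyme gene of myeloid cells, was at 0.05 CPM in CLEC (0.02 to 0.10) and 9175 in macrophages. C1qb, a complement gene, was at 0.03 CPM (0.01 to 0.07) and 7028, and Tyrobp, an immune receptor adaptor gene, was at least 89615-fold lower. All 12 pan-endothelial genes were higher in CLEC, with a median of 8.72 (7.41 to 9.81), or 9.09 at the bound. Egfl7, an endothelial matrix gene, was at 1163 and 0.05 CPM, and Cldn5, a tight junction gene, at 1842 and 0.10 CPM.

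By the naming rule 1120 genes were higher and 969 lower, of 11551 measured. The highest ratios among those not already given were those of Igfbp7 (11.80), Col4a2 (10.99), Lrg1 (10.88) and Sparcl1 (10.82). Ctss (-12.82) and Apoe (-11.09), an apolipoprotein gene, were among the lowest. All 8 haematopoietic genes (median -7.82), all 3 measured alternative activation genes (-7.86), all 5 MHC class II genes (-5.57) and 4 of 6 inflammatory genes (-3.78) were lower. One B cell gene, 1 dendritic cell gene, 1 neutrophil gene and 1 epithelial gene were measured, each lower in CLEC, with ratios of -5.45, -7.29, -6.73 and -3.19, or -11.08 and -8.69 at the bound for the B cell and epithelial genes. All 13 blood endothelial genes were higher, with a median of 8.31 (5.99 to 9.78), or 10.15 at the bound. Shuffled gates gave at most 130 genes against 2089. The macrophages were on their own plate, and with a pseudocount of 5 CPM the macrophage and pan-endothelial medians were -7.19 and 6.59.

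LN GFP+ cells were compared with LN GFP- endothelial cells of the same pools, which asks the same question in the lymph node. Blood endothelial genes were far lower in the GFP+ cells. Of 13 members 12 were lower, with a median log2 ratio of -6.61 (-9.39 to -3.85), or -7.85 at the bound. Ly6c1 was at 990 CPM in GFP- cells and had 0 reads in GFP+ cells, at least 31369-fold lower, and Cd34 was at 0.64 CPM (0.49 to 0.82) and 1098 (1089 to 1108). All 6 capillary genes were lower (median -6.17, or -9.06 at the bound, and 0.00 in pool C), with Cd36, a fatty acid transporter gene, at 0.06 CPM (0.02 to 0.14) and 1545. Cd36 does not mark capillary cells alone here. In the clusters described below it was at 3717 CPM in the lymphatic-like cluster led by Pkhd1l1, with reads in 95% of cells. In the blood-like cluster led by Cxcl12 it was at 822 CPM, with reads in 44.8%.

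Genes of the lymphatic endothelium of the lymph node separated into groups. Of 6 sinus floor genes 5 were higher in GFP+ cells, with a median of 3.88 (0.87 to 5.76), and 8.35, 3.05 and 8.69 in pools A, B and C. Madcam1 (chromosome 10, 79664559 to 79668537, plus strand), an adhesion molecule gene, was at 1580 CPM in GFP+ cells and 106.6 in GFP- cells, with reads in 91.8% and 10.8% of cells, or 91.6% and 8.45% when thinned. Itga2b, an integrin gene, was at 617 and 10.4 CPM, and Coch at 2520.5 and 138.2. All 5 sinus ceiling genes were lower (median -8.45, or -8.51 at the bound), among them Bmp4, at 0 reads and 51.4 CPM. The lymphatic list as a whole had 3 members higher, 2 lower and 6 within 2-fold, with a median of 0.48 (-2.36 to 1.64). Lyve1 was at 590 CPM (585 to 595) and 113.9 (110.8 to 116.9), and Maf at 162.5 and 51.6, whereas Mmrn1 was at 72.03 and 373.4.

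By the naming rule 395 genes were higher and 360 lower, of 11140 measured. Clec4g (chromosome 8, 3707064 to 3720651, minus strand), a C-type lectin gene, was at 330.8 CPM in GFP+ cells and had 0 reads in GFP- cells, at least 5259-fold higher. Mme and Igsf10 also had 0 reads in GFP- cells and were at least 1767-fold and 1167-fold higher. Postn, the matrix protein gene periostin, was at 2690.2 and 46.7 CPM, a ratio of 5.82. Zeb2, Scg5, Unc5c, Cfp and Chrnb4 followed, with ratios of 5.50 to 5.09. Shuffled gates reached 5.33, so the ratios of Unc5c, Cfp and Chrnb4 are within what shuffled gates give. Besides those given, Ly6a, Sparcl1, Tinagl1 and Id1 were among the lowest, with ratios of -9.39, -9.11, -8.66 and -8.58, the last pair against 0 reads.

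Pan-endothelial genes were lower too, 9 of 12, with a median of -1.50 (-2.75 to -0.78), and Pecam1 itself was at 622 and 1902 CPM. High endothelial venule genes had 5 of 8 lower (median -2.48) and 1 higher, and arterial genes had 6 of 9 lower (-1.78, with -1.93, -0.20 and -4.14 in pools A, B and C). Venous genes had 4 of 7 lower (-1.10), angiogenic tip genes 5 of 9 lower (-2.20), and medullary lymphatic genes 1 higher and 2 lower of 3 (-3.39, but 0.18 in pool C). All 5 measured macrophage genes were higher (median 1.99). Of these Ctss was at 454 and 52.1 CPM, and Csf1r at 3.48 (3.12 to 3.88) and 0.13 (0.05 to 0.27), while Adgre1, C1qa and Itgam fell under the measured level. Both measured fibroblast or pericyte genes were higher: Rgs5 at 265.3 and 8.95 CPM and Ccl19 at 25.5 and 3.15. Of 3 measured platelet genes 2 were higher, Itga2b among them. Interferon and dissociation stress genes each had 4 of 10 lower, with medians of -0.67 and -0.89, which in pool C, with 8 GFP- cells, were 3.63 and 1.74.

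Csf1r reads were found in 39 of 98 GFP+ cells (39.8%, 30.04 to 50.18) and in 3 of 74 GFP- cells (4.05%, 0.84 to 11.4). With 95 and 71 cells thinned to 100000 reads, which left out 3 of each, the shares were 20.0% (12.5 to 29.5) and 2.82% (0.34 to 9.81). The GFP- cells serve as the background for this gene. No shuffle of the gates gave as many as the 755 genes of the real gates, and 7 genes lay above and 75 below all shuffled ratios. The lymphatic median ranged from -0.02 with the stricter cell filter to 1.08 with thinned cells, so no direction is given for it.

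LN GFPlow cells were compared with GFP- and GFP+ cells in pools B and C, the pools that hold all 3 gates (29 GFPlow, 34 GFP- and 55 GFP+ cells). Against GFP- cells, 12 of 13 blood endothelial genes were lower, with a median log2 ratio of -8.45 (-9.62 to -1.40). All 6 sinus floor genes were higher, with a median of 2.22 (1.69 to 4.28), and 2.07 and 7.88 in pools B and C, Itga2b at 398 and 19.6 CPM and Madcam1 at 735 and 202.1 CPM. Of 5 sinus ceiling genes 4 were lower (-2.58), and of 5 lymphatic valve genes 4 were higher (1.38). The lymphatic list had 3 members higher, 2 lower and 7 within 2-fold, with a median of 0.31 (-0.52 to 1.75), and -0.13 and 1.75 in pools B and C.

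Against GFP- cells 439 genes were higher and 418 lower, of 10613 measured. Cfp, the properdin gene of the complement system, was at 169.96 CPM and had 0 reads in GFP- cells, at least 1425-fold higher, and Ptgr1, a prostaglandin reductase gene, was at 307.3 and 1.19 CPM. Cxcl12, a chemokine gene, was at 0.03 CPM in GFPlow cells (0.00 to 0.19) and 2455 in GFP- cells, and Sparcl1 and Flt1 had 0 reads in GFPlow cells, at least 10688-fold and 7130-fold lower. Macrophage genes had 4 of 5 higher (2.00, or 2.52 at the bound), with medians of 0.10 in pool B and 2.59 in pool C. Against GFP+ cells, 9 of 11 lymphatic genes and 4 of 6 sinus floor genes were within 2-fold, with medians of 0.15 (-0.93 to 0.91) and -0.56 (-1.15 to 0.69). With cells of named clusters alone 4 lymphatic genes were higher, and without pool C 3 were higher and 4 lower, so this likeness depends on the setting. Pan-endothelial genes had 9 of 12 within 2-fold, and MHC class II genes had 2 of 4 lower (-1.14).

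Shuffled gates gave 424 to 653 genes for GFPlow against GFP-, where the real gates gave 857, and 19 genes lay below all shuffled ratios and 0 above. The ratios of Cfp and Ptgr1 (7.42 and 7.14) are thus within what shuffled gates reach (7.79). For GFPlow against GFP+ they gave up to 549 where the real gates gave 519, 2 of 100 shuffles gave as many, and 0 genes lay beyond the shuffled ratios. The number of genes apart between GFPlow and GFP+ cells was thus near the upper end of the shuffles and not beyond it, and none is singled out by name. Pool C held 14 GFPlow and 8 GFP- cells, and without it the counts against GFP- cells were 745 and 710 and against GFP+ cells 609 and 512.

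Blood GFP+ cells were compared with LN GFP+ cells to ask whether cells of the same gate in blood carry the same genes. Pan-endothelial genes were lower in the 7 blood cells, 12 of 12, with a median log2 ratio of -6.30 (-8.21 to -2.60), or -6.65 at the bound. Haematopoietic genes were higher, 8 of 8, with a median of 6.17 (2.59 to 9.91). Laptm5, a lysosomal membrane gene of leukocytes, was at 1700 CPM in blood and 0.77 in LN GFP+ cells. B cell genes were higher, 4 of 4, with a median of 8.10, or 12.60 at the bound, and Cd79a, a gene of a subunit of the B cell receptor, had reads in 5 of the 7 cells and none in LN GFP+ cells. Plasma cell genes had 3 of 4 higher (5.18, or 7.67 at the bound).

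By the naming rule 1186 genes were higher and 1509 lower, of 11165 measured. Igkc, the immunoglobulin kappa constant gene, was at 27282 CPM in blood (27136 to 27428) and 1.30 in LN GFP+ cells, and Ighm, the mu heavy chain gene, was at least 128483-fold higher. Clu, a secreted chaperone gene, was at 10.3 and 24823 CPM, Glycam1 at 1.01 and 2674, and Coch and Vcam1 had 0 reads in blood cells, at least 4155-fold and 2329-fold lower. Lymphatic genes had 9 of 10 lower (-7.18, or -7.53 at the bound), and macrophage genes had 8 of 11 higher (3.60, or 5.23 at the bound). T cell genes had 3 of 3 higher (2.39), both measured dendritic cell genes were higher (6.99, or 9.47 at the bound), and 4 of 7 platelet genes were higher and 3 lower. One erythroid gene was measured and was higher (3.25, or 8.07 at the bound). Ptprc, which the gate was to exclude, had reads in 5 of 7 cells, and Pecam1 in 3 of 7. Shuffled gates gave 1244 to 1907 genes against 2695. No pool held at least 5 passing cells of both groups, so no value within a pool can be given, and the median of all measured genes was itself at -1.40.

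Tumour CLEC were compared with LN GFP+ cells, the same gate in another tissue. Blood endothelial genes were higher in tumour CLEC, 11 of 13, with a median log2 ratio of 6.90 (4.57 to 9.32), or 8.61 at the bound. Cd34 was at 1582 CPM (1576 to 1589) and 0.64 (0.49 to 0.82), and Cd93 and Ly6c1 had 0 reads in LN GFP+ cells, at least 35819-fold and 22598-fold higher. Lymphatic genes were lower, 8 of 10, with a median of -4.48 (-6.09 to 0.68), Lyve1 at 14.04 and 590 CPM and Sema3d at 1.26 and 153.1. Flt4 was within 2-fold, at 292.5 and 182.8 CPM. All 6 sinus floor genes were lower (median -10.83 with genes at 0 reads at their bound), and Madcam1 and Coch had 0 reads in tumour CLEC, at least 80249-fold and 128020.2-fold lower.

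By the naming rule 986 genes were higher and 698 lower, of 11538 measured. Sparcl1 and Ly6a were among the highest, with ratios of 10.07 and 9.21. Postn was at 0.03 CPM in tumour CLEC and 2690.2 in LN GFP+ cells, and Glycam1, a ligand gene of high endothelial venules, at 0.18 and 2674. Besides those given, C3, Cyp1b1, Serpina3n and Mmp9 had 0 reads in tumour CLEC and were at 2502, 1424, 1316 and 1144 CPM in LN GFP+ cells. Angiogenic tip genes were higher, 11 of 12, with a median of 4.76 (2.80 to 7.25), or 5.60 at the bound. Proliferation genes were higher, 11 of 12 (4.08, or 5.94 at the bound), with Top2a at 93.5 CPM and 0 reads and Mki67 at 94.2 and 8.42 CPM. Hypoxia genes had 8 of 10 higher, with a median of 2.05 (0.69 to 2.85), and Eno1, a glycolytic enzyme gene, at 1098 and 151.1 CPM. Arterial genes had 6 of 9 higher (4.44, or 6.89 at the bound) and capillary genes 3 of 3 (5.75, or 9.42 at the bound). Lower lists were MHC class II, 4 of 4 (-2.28), with Cd74 at 134.96 and 2196 CPM, and interferon response, 8 of 10, with a median of -1.78 (-3.15 to -0.53).

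Dissociation stress genes were also lower in tumour CLEC, 8 of 10, with a median of -1.53 (-2.89 to -0.70), with Fos at 313.9 and 2496 CPM. Xist, the transcript of the inactive X chromosome, had reads in 79.9% of tumour CLEC and 10.2% of LN GFP+ cells, and a Y-linked gene (Ddx3y, Eif2s3y, Kdm5d or Uty) in 2.37% and 54.1%. In tumour EC these shares were 84.5% and 2.38%, and in LN GFP- cells 6.76% and 52.7%. Shuffled groups gave 35 to 84 genes against 1684. The plates of 1 tissue held no cell of the other, so tissue and plate cannot be separated in this comparison.

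**Figure D4:**
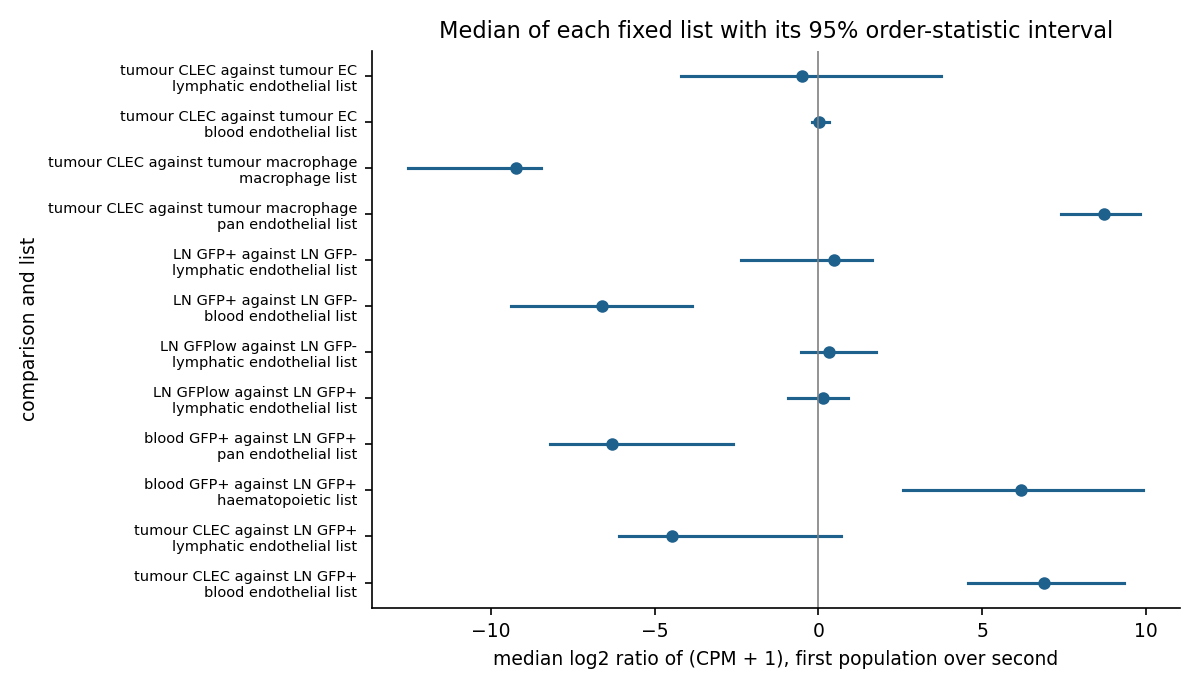
Median log2 ratio (points) of the lists fixed for each comparison, with the 95% interval from the order of their members (lines), first population over second. Blood endothelial genes lie at 0.01 between the tumour gates, at -6.61 between the LN gates and at 6.90 between tumour CLEC and LN GFP+ cells.

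Prox1 (chromosome 1, 190118035 to 190170714, minus strand) encodes the transcription factor that sets lymphatic endothelial identity, so its share of cells was compared across the gates. It had reads in 78 of 98 LN GFP+ cells (79.6%, 70.3 to 87.1) and in 27 of 74 LN GFP- cells (36.5%, 25.6 to 48.5), a share that was 23.3% with no cell filter and 51.02% with the stricter one. In tumour CLEC 1 cell had Prox1 reads (0.59%, 0.01 to 3.25), and in tumour EC 0 of 84, which allows a share of up to 3.57%. The 1 tumour cell was on plate KM4, and without that plate the share was 0 of 84. Lyve1 had reads in 10.7% of tumour CLEC, 15.5% of tumour EC and 71.4% of LN GFP+ cells, or 8.38%, 15.9% and 65.3% when thinned. Macrophages, which should lack Prox1, had reads in 0 of 81 cells (up to 3.70%), and the LN GFPlow cells of all pools had them in 59 of 79 (74.7%, 63.6 to 83.8).

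With cells thinned to 100000 reads, Prox1 had reads in 73.7% of 95 LN GFP+ cells (63.7 to 82.2), 30.99% of 71 LN GFP- cells (20.5 to 43.1) and 0.60% of tumour CLEC (0.02 to 3.29). This left out 3, 3 and 2 cells. By pool, the share among LN GFP+ cells was 74.4% in pool A, 87.9% in pool B and 77.3% in pool C, and among LN GFP- cells 35%, 46.2% and 12.5%.

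Clusters were named by their markers. In the lymph node 79.6% of GFP+ cells (70.3 to 87.1), 31.1% of GFP- cells (20.8 to 42.9) and 73.4% of GFPlow cells (62.3 to 82.7) lay in lymphatic-like clusters. By pool the GFP- share was 27.5% in pool A, 46.2% in pool B and 0 of 8 cells in pool C, and it was 48.98% with the stricter cell filter. The GFPlow share was 73.3% in pool B, 42.9% in pool C and 82% in pool D. Blood-like clusters held 56.8% of LN GFP- cells, 0 of 98 GFP+ cells (up to 3.06%) and 2.53% of GFPlow cells. All lymphatic-like GFP+ cells were in 1 cluster, led by Abhd8, Rgs4 and Asrgl1, whereas 17 of 23 lymphatic-like GFP- cells were in another, led by Pkhd1l1, Pdlim3, Mfap2 and Ackr4. The 2 blood-like clusters of the lymph node were led by Cxcl12, Sox17 and Esm1 and by Fut7, an enzyme gene of high endothelial venules, Chst4 and Ccl21a.

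In the tumour 0 CLEC and 0 EC lay in a lymphatic-like cluster, which by the number of cells allows shares of up to 1.78% and 3.57%. These limits do not cover lymphatic cells too few to form a cluster of their own. The smallest tumour cluster held 23 cells, and the 1 CLEC with Prox1 reads was in the unnamed cluster. Blood-like clusters held 71.6% of CLEC (64.2 to 78.3) and 91.7% of EC (83.6 to 96.6). Within them, the cluster led by Angpt2, Prnd and Nox4 held 40.8% of CLEC and 42.9% of EC. The cluster led by Itm2a, Scgb3a1 and Slc39a8 held 21.3% and 40.5%, and the cycling cluster led by Fam83d, Fam64a and Mxd3 held 9.47% and 8.33%. The other tumour endothelial cells, 28.4% of CLEC and 8.33% of EC, were in a cluster left unnamed, with a median of 384214 reads. At a clustering resolution of 0.5 none were unnamed, and with thinned cells 16.77% and 6.10% were and with the stricter cell filter 31.4% and 2.53%, so the gap between the gates in blood-like shares rests on this cluster. In it 12 of 13 blood endothelial markers had reads in at least 30% of cells. In the lymph node, 20.4% of GFP+, 12.2% of GFP- and 24.1% of GFPlow cells were unnamed, with a median of 439180.5 reads. All 81 macrophages lay in 1 macrophage-like cluster. Of the 7 blood cells 3 fell into the lymphatic-like cluster although 0 of 7 had Prox1 reads, so with so few cells the cluster name says little of them.

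**Figure D5:**
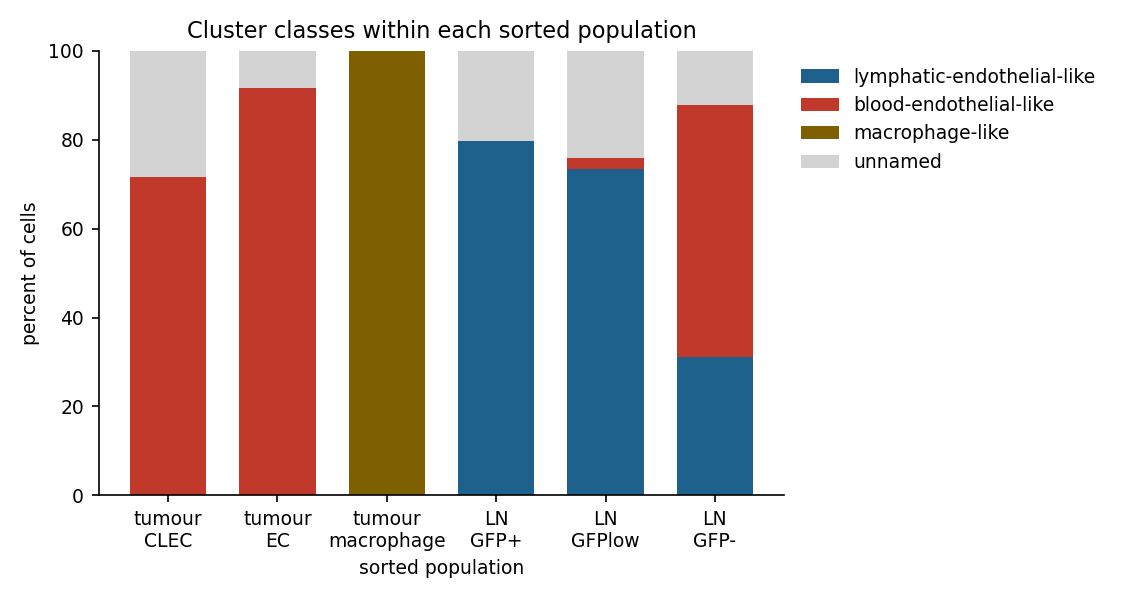
Percent of cells in each cluster class for 6 sorted populations, as stacked bars of 0 to 100. Lymphatic-like clusters hold 79.6% of LN GFP+, 73.4% of LN GFPlow and 31.1% of LN GFP- cells and 0 tumour cells, and blood-like clusters hold 71.6% of tumour CLEC and 91.7% of tumour EC.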

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

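The tests of read depth, of carry-over between wells, of RNA with the tumour macrophage profile and of the sampling of cells were chosen after the results they bear on had been seen.

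Among the genes named by the rule, 4 were higher in GFP+ than in GFP- endothelial cells in the tumour on both plates and lower in the lymph node in every pool. Aqp1 had log2 ratios of 3.13 in the tumour and -9.76 in the lymph node, Fabp4 of 4.76 and -8.51, Kctd12 of 1.98 and -1.39, and Slc6a6 of 2.26 and -1.47. Shuffled gates reached 4.53 in the tumour and -4.17 in the lymph node. Only Fabp4 lay beyond both, and Aqp1 beyond the lymph node value alone. The ratios of Kctd12 and Slc6a6 are within what shuffled gates give in both tissues. How many genes would show such opposite ratios with shuffled gates was not tested. In the lymph node, blood-like clusters held 56.8% of GFP- and 0 of 98 GFP+ cells, so those gates also differ in endothelial class. In the tumour they held 71.6% of CLEC and 91.7% of EC. Whether the ratios follow this mix of cells was not tested, nor was the difference between tissues. The 2 empty wells of pool D, which no comparison uses, held 59 and 82 reads in genes, with no control well to set them against. Pool D also held GFPlow cells whose levels no comparison of gates uses, and 80% of them (40 of 50), which are part of the GFPlow share given above, had Prox1 reads, against 36.5% of LN GFP- cells.

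Prox1 reads were found in few tumour CLEC and in most LN GFP+ cells. Lower depth is argued against: with every cell thinned to the same reads the LN GFP+ share was 73.68%, far above the upper bound of 3.29% in tumour CLEC. Xist marked most tumour cells and few LN cells. Among LN GFP+ and GFPlow cells with at least 5 Xist reads, 80% (8 of 10, 44.4 to 97.5) had Prox1 reads. These cells were chosen by Xist alone and not checked for Y-linked reads, so this cannot decide whether sex is a cause. This test was first run by mistake without the GFPlow cells and was then run on both gates as planned. Among cells of the lymph node and blood pools, Prox1 reads were in most cells of both lymphatic-like clusters and few of both blood-like ones. Most tumour CLEC lay in blood-like clusters, so the pattern goes with endothelial class. The 2 lymphatic-like clusters were formed without the list genes but named by 8 and 9 of 13 lymphatic markers. This link is therefore partly by construction. A plate effect that lowers endothelial genes alike is argued against. In every pair of plate and pool the blood endothelial median was higher in tumour CLEC and the lymphatic median lower. With 0 plates or pools holding both tissues, other differences between plates and pools cannot be told apart from a difference between tissues. Either may contribute to the pattern.

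Csf1r reads were found in a larger share of LN GFP+ than of GFP- cells, at a few CPM. Carry-over between wells of a pool stays open: GFP- wells of the same pools held 3.62% of the CPM of GFP+ wells, but this restates the pattern. RNA from cells like the tumour macrophages is argued against, because C1qa, C1qb and C1qc reached at most 0.20% of the CPM they would then have, with 6 reads in all, and the gate excluded CD45+ cells. RNA of other macrophages stays open, as 23 other genes of the macrophage and haematopoietic lists had a median of 0.187 of the CPM expected from Csf1r (interval of the median 0.0118 to 4.78), with 11 under 0.1 and Ctss and Lyz2 above what was expected. An introduced sequence that holds a part of Csf1r could also give such reads, and with 0 tables of read positions inside a gene it stays open, as does a low level of Csf1r in these endothelial cells.

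Genes met the rule, on both CLEC plates, as higher or lower in tumour CLEC than in tumour EC. Sampling of cells is argued against as the whole cause, since shuffled gates gave at most 87 genes. Simulated cells with no gene changed gave fewer genes than the real gates, but nearly as many. The larger unnamed cluster among CLEC is also argued against as the whole cause. Without unnamed cells, 86% of the genes were still 2-fold apart. A difference between plates stays open. The 2 CLEC plates were themselves apart in 51.8% as many genes as a CLEC plate and the EC plate on average. With 0 plates holding both gates, an effect of the EC plate could account for part or all of the genes, and a difference between the gates may do so as well.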

How the results depend on the processing

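The alternatives for the numbers of genes, cells of named clusters alone and pool C left out, were chosen after seeing the data. The others were planned. Of the planned ones 7 moved a result out of its interval and 0 gave the other sign to a list median whose interval leaves out 0. For list medians this interval reflects the spread between members and can be wide, so staying within it says little about how far a median shifted. Medians whose interval spans 0 did change sign, as in the tumour lymphatic list (-1.73 to 0.76). Among list medians 2 moved, among Prox1 shares 3 of 24 and among cluster shares 2 of 28. A pseudocount of 5 CPM moved the macrophage and pan-endothelial medians of tumour CLEC against macrophages to -7.19 and 6.59, which a larger pseudocount does by construction for genes near 0. No cell filter gave Prox1 in 23.28% of LN GFP- cells and the stricter filter in 51.02%. The stricter filter placed 100% of LN GFP+ and 48.98% of LN GFP- cells in lymphatic-like clusters, and 0 of them were then in an unnamed one. The cause of these changes was not tested. Leaving out a plate gave tumour CLEC Prox1 shares of 0.00 to 1.18%, as the 1 cell with reads is on plate KM4.

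Leaving out plates or pools in turn gave medians of -1.15 to -0.18 (lymphatic) and -0.13 to 0.17 (blood) for tumour CLEC over EC, so the blood median changed sign near 0. The ranges were -9.26 to -9.20 (macrophage) and 8.65 to 8.78 (pan-endothelial) against macrophages, and 0.13 to 0.40 (lymphatic) and -6.75 to -6.19 (blood) for LN GFP+ over GFP-. GFPlow cells gave lymphatic medians of 0.30 to 1.75 over GFP- (in pool B alone -0.13 over the members measured with pool C included) and 0.11 to 0.43 over GFP+ cells. Blood over LN GFP+ cells gave -6.38 to -6.29 (pan-endothelial) and 5.91 to 7.10 (haematopoietic). Tumour CLEC over LN GFP+ cells gave -4.78 to -3.93 (lymphatic) and 6.69 to 7.23 (blood). Prox1 shares ranged from 75.38 to 83.64% in LN GFP+ and 31.25 to 39.39% in LN GFP- cells.

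Counts of genes by the rule moved in 2 comparisons. For GFPlow over GFP- cells, 439 higher genes became 705 with named clusters alone and 745 without pool C, and 418 lower genes became 721 and 710. For GFPlow over GFP+ cells, with 519 genes in all as reported, the higher genes became 398 and 609 and the lower ones 448 and 512. Without pool C the rule asks for 1 pool fewer to show the same direction. For named clusters the cause was not tested. Lymphatic genes at least 2-fold higher or lower over GFP- cells became 5 (higher, named clusters) and 4 (lower, without pool C), and over GFP+ cells 4 and 3 higher and 4 lower.

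The settings not run for blood were leaving out pool D, which left 1 blood cell, and using named clusters alone. A planned setting with pool B alone for both groups was run. It rests on the same 1 blood cell, so its medians are not given and are not in the ranges above. No paired analysis was possible because no label says which animal a cell came from, and pools served only to compare gates within each of them. The number of cells limits what a share of 0 can show, since 0 in 84 cells allows up to 3.57%. This limit does not cover reads missed at low depth, and intervals cover counting error only.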
